A study of Homo sapiens with 2 samples.

How the data were processed

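Total RNA was extracted with Trizol from cells of the line called 231 in the labels, and libraries were made by a standard Illumina procedure, per the labels' protocols. One group was transfected against YBX1 with a reagent that the labels call an siRNA and the design text a Smart Silencer, and the other is labelled siNC. Each group had 1 library, taken 48 h after transfection.

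The authors deposited 1 table per library with a gene identifier, a symbol and an FPKM value, per the file headers. The submitters' processing notes name cutadapt 1.17, HISAT2 2.1.0, StringTie 1.3.3 and the GRCh37 build, without giving their roles or order. The annotation release, the handling of strand and the rule by which genes were listed are not given in the sources used here. The FPKM values are relative to transcript length and library size, and no counts accompany them. The depth is therefore unknown, and no counting interval or detection floor was computed. Reads that fit several genes can have been divided between near-identical or overlapping genes in a way the values do not show. Because FPKM are scaled to length, a sum of FPKM over genes of unlike length does not add up their reads.

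The tables listed different genes. Of the 11678 genes in the siYBX1 table and the 13017 in the siNC table, 11476 were in both, 202 only in the siYBX1 table and 1541 only in the siNC table, with medians of 0.676 and 0.109 FPKM for the latter sets. Genes under 0.5 FPKM made up 2.23% of the siYBX1 table and 12.0% of the siNC table, and 25 and 420 genes were listed at 0. A low gene missing from the siYBX1 table was thus not read as absent in the main comparison, while the marker counts in the closing section took a missing gene as lower. To test this listing, 1 of the 200 genes nearest in value was drawn for each marker, 10000 times. The summed FPKM was 222872 and 201233.

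Differences were computed as log2(FPKM + 1) in the siYBX1 library minus the siNC library, for genes listed in both with a mean of at least 1 FPKM, and a gene was counted as higher or lower from a difference of 1 (2-fold) on this scale, which understates the differences of low genes. With 1 library per group no test across samples was possible, and no p-value or standard deviation between replicates is given. Ratios of FPKM, where given, use no pseudocount, and none was formed against a gene listed at 0.

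For each gene list, the median difference of its compared members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list of at least 5 genes was described as standing apart at a percentile of at most 2.5 or at least 97.5. These percentiles describe the pair of libraries and not the conditions, and some genes, such as CDKN1A, MYC, JUNB and COL1A1, belong to several lists. Members were matched by symbol, or by gene identifier through older symbols.

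The genes named in the text followed a rule written before the data were examined, as were the lists, the groups, the measures and 10 of the alternatives. It takes YBX1, YBX2 and YBX3, the 12 genes with the largest difference each way among those with a mean of at least 5 FPKM and a value above 0 in both libraries, up to 4 members per list with the largest differences, up to 3 genes per direction listed at 0 in 1 library, and the 5 genes with the highest mean. From the 24 ranked genes it leaves out clone-based names, small RNAs, mitochondrially encoded genes and XIST and Y-linked genes. Other list members named, TGFB2 and MCL1, were chosen after their values were seen. Some genes that the rule admits are not reported here.

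The alternatives fixed beforehand were pseudocounts of 0.1 and 5, centring on the median, scaling to the same total or upper quartile, no filter on low values, a mean of at least 5 FPKM, leaving out genes listed at 0, summing rows with a shared symbol, and unmatched random lists. The 4 others were chosen after seeing the data: genes listed in 1 table taken as 0 in the other, removal of a length and GC trend, leaving out read-through genes and their parts, and matching random lists on coding length. The trend was fitted by least squares on B-splines with 5 degrees of freedom each for log2 transcript length and GC content. Transcript length, GC content, coding length and overlaps between genes came from GENCODE 29 on GRCh38, not from the authors' build, so no coordinates are given. Length and GC content were those of each gene's longest protein-coding transcript, which need not be the one expressed. In all, 99.3% of the compared genes had a length. Genes taken as read-through were those with a hyphenated name of which at least 1 part is itself a listed gene. Names starting with MT-, HLA- or KRTAP were not taken. This rule can also take in genes that are not read-throughs. Added to them were 129 clone-named genes that overlap at least 2 listed genes on the same strand.

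The procedure was tested on simulated data for the comparison of the libraries over 10548 genes with a noise of 0.61 (SD, log2 scale). It called 80% of genes given a log2 change of 1.5 and 100% of those given 3. These changes were given only to genes at 5 FPKM or more in the siNC library, so lower genes were not tested. Of unchanged genes, 10.01% passed 2-fold, 4.97% up and 5.04% down, against 7.20% higher and 5.62% lower in the real libraries. That noise equals the central spread of the real differences, so it holds any true small ones too. Of 200 lists of randomly drawn genes without a shift, 4.5% stood apart, and 100% of 20 such lists shifted by 0.8 were found. Lists of genes that vary together were not simulated. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, patsy 1.0.2 and matplotlib 3.10.9.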

Results

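RNA sequencing was used to compare a human breast cell line after transfection against YBX1 with the same line after transfection with a control labelled siNC. The labels call the line 231, a name in common use for MDA-MB-231, an invasive breast cancer line, but they do not spell it out. YBX1 encodes the cold shock domain protein YB-1, which binds DNA and RNA. The question, as the labels state it, was how the transcriptome differs once YBX1 is knocked down. Each group held 1 library, taken 48 h after transfection, so there were no replicates and no difference below has a replicate check. The deposited values were FPKM, fragment numbers scaled to transcript length and library size, without counts, so the depth is unknown and no counting interval can be given. The siYBX1 library listed 11678 genes with a median of 5.91 FPKM, and the siNC library listed 13017 genes with a median of 4.74 FPKM. In all, 10484 and 10478 genes reached 1 FPKM in them.

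YBX1 (ENSG00000065978.18_3) was listed at 38.1 FPKM in the siYBX1 library and at 649 FPKM in the siNC library, 17.0-fold lower after the knockdown and a difference of -4.05 in log2(FPKM + 1). Its paralog YBX3 stood at 9.71 against 15.2 FPKM (log2 difference -0.59). YBX2, the germ cell member of the family, was listed at 0 in the siNC library and was not listed in the siYBX1 library. CARHSP1, another cold shock domain gene, was higher in the siYBX1 library, at 10.0 against 3.70 FPKM (1.23).

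Among 10548 genes listed in both libraries with a mean of at least 1 FPKM, 759 were at least 2-fold higher and 593 at least 2-fold lower in the siYBX1 library on the log2(FPKM + 1) scale, and 9196 lay within 2-fold. At 4-fold the numbers were 59 higher and 31 lower. The highest mean FPKM belonged to the mitochondrial transcripts MT-CO2, MT-ND4, MT-CO1, MT-CO3 and MT-ATP8, and mitochondrially encoded mRNA made up 21.5% of the summed FPKM in the siYBX1 library and 18.0% in the siNC library. The split between higher and lower genes depended on the scale: with both libraries scaled to the same total, 571 genes were higher and 821 lower, and with the same upper quartile 614 were higher and 778 lower. The median difference of all genes was 0.02 as deposited and -0.10 at the same total, so small differences carry no direction of their own. The log2 values of both libraries correlated across genes with Pearson's r = 0.892 and Spearman's rho = 0.877, where genes are not independent replicates.

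**Figure D1:**
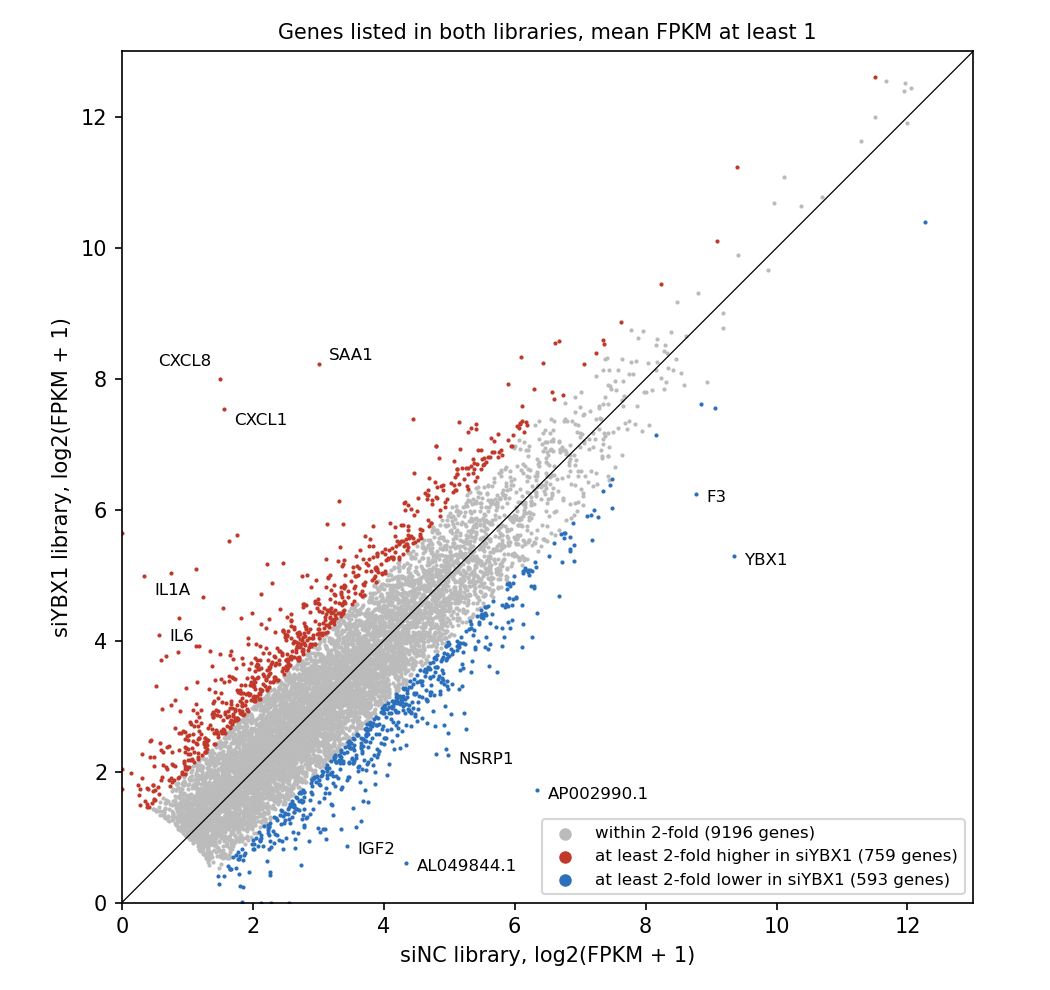
Each point is 1 of 10548 genes, with log2(FPKM + 1) of the siNC library on the x axis and of the siYBX1 library on the y axis, and the line marks equal values. The 759 red genes lie at least 2-fold above the line, with CXCL8, CXCL1 and SAA1 far from it, and the 593 blue genes at least 2-fold below it, with YBX1 at 38.1 against 649 FPKM.

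The genes with the largest positive differences were mostly secreted inflammatory proteins. The neutrophil chemoattractants CXCL8, CXCL1 and CXCL2 were listed at 256, 186 and 24.4 FPKM in the siYBX1 library and at 1.83, 1.95 and 1.36 FPKM in the siNC library, log2 differences of 6.50, 5.98 and 3.42. The cytokines IL1A (30.6 against 0.268 FPKM, 4.64), IL6 (16.0 against 0.482 FPKM, 3.52) and IL1B (19.3 against 0.824 FPKM, 3.48) were also higher. The acute phase genes SAA1 and SAA2 stood at 299 and 31.7 FPKM against 7.06 and 0.685 FPKM. These neighbours are near-identical and can exchange reads, and summed with their read-through gene they came to 334 against 7.74 FPKM. ZC3H12A, an RNase that degrades cytokine mRNAs, was at 33.3 against 1.20 FPKM (3.97). The others of the 12 were C15orf48 (45.0 against 2.103 FPKM, 3.89), KRTAP2-3 (48.0 against 2.37 FPKM, 3.86) and the MHC class II gene HLA-DRA (12.1 against 0.516 FPKM, 3.11). CSF2, the granulocyte-macrophage growth factor GM-CSF, was listed at 48.8 FPKM in the siYBX1 library and at 0 in the siNC library. Also listed at 0 in the siNC library were SAA2-SAA4, at 3.12 FPKM in the siYBX1 library, and TRIM39-RPP21, at 2.33 FPKM. Both are read-through genes that can share reads with the genes they span, so their single values are uncertain.

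After YBX1, the largest negative differences among the genes named by the rule were those of NSRP1, a regulator of splicing, at 3.76 FPKM in the siYBX1 library against 30.7 FPKM (-2.73), of the receptor gene FGFRL1 at 4.06 against 30.0 FPKM (-2.62) and of RIPOR1 at 5.31 against 37.2 FPKM (-2.60). F3, the tissue factor that starts blood clotting, was 5.85-fold lower, at 74.6 against 436 FPKM (-2.53). Also lower were IGF2 (0.823 against 9.79 FPKM, -2.57), IGFBP1 (3.82 against 26.7 FPKM, -2.52), IGFBP3 (5.05 against 30.6 FPKM, -2.39) and the activin antagonist FST (1.89 against 12.5 FPKM, -2.23). The complement inhibitor CD55 stood at 6.46 against 36.3 FPKM (-2.32), FBXL14 at 1.23 against 10.9 FPKM (-2.41) and MNS1 at 1.38 against 11.6 FPKM (-2.40). Liver is a main source of IGF2 and IGFBP1, and several hepatocyte genes, among them ALB at 10.4 FPKM, were listed in the siNC library and not in the siYBX1 library. The rule left out clone-based names, and AP002990.1, at 2.28 against 80.3 FPKM (-4.63), and AL049844.1, at 0.520 against 19.3 FPKM (-3.74), which were chosen after their values were seen, had larger negative differences than NSRP1. Both span neighbouring genes on the same strand. AP002990.1 overlaps EEF1G, which was higher in the siYBX1 library (373 against 96.8 FPKM). AL049844.1 overlaps LTV1, which stood at 44.6 against 72.9 FPKM. Because of these overlaps the single values of both are uncertain. Summed with the listed genes that each overlaps, AP002990.1 came to 378 against 178 FPKM and AL049844.1 to 48.1 against 95.2 FPKM. These sums do not add up reads where lengths differ. FAM47E-STBD1, BIVM-ERCC5 and AL136295.1, which also span other genes, were listed at 0 in the siYBX1 library and at 4.87, 3.86 and 3.36 FPKM in the siNC library.

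**Figure D2:**
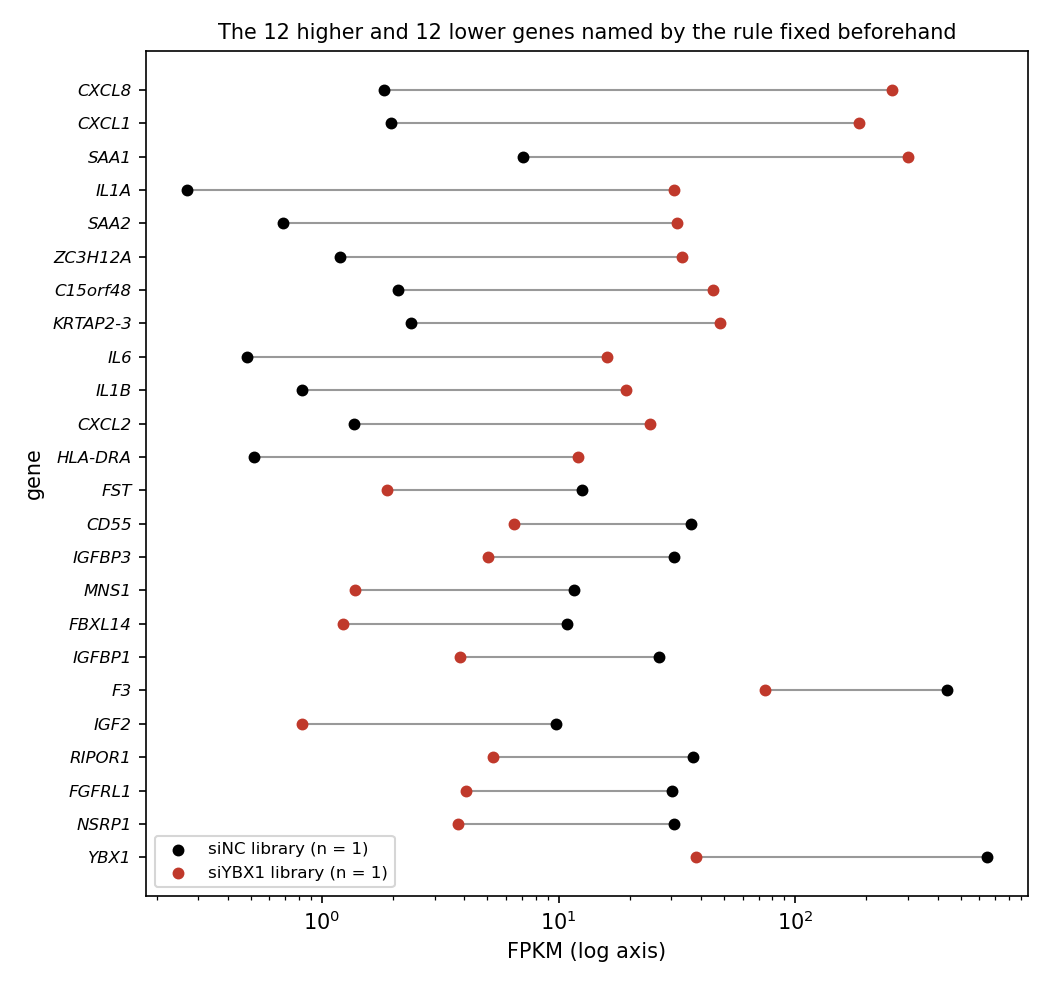
FPKM on a log axis of the 12 higher and 12 lower genes with the largest differences among those the rule admits, with black points for the siNC library and red points for the siYBX1 library (n = 1 each). CXCL8 spans 1.83 to 256 FPKM and YBX1 spans 38.1 to 649 FPKM.

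Of 52 gene lists fixed before the data were examined, 47 held at least 5 compared genes. The median difference of 18 of these stood apart from random lists matched on expression, 16 at the high end and 2 at the low end. For lists of unrelated genes, 2.35 would be expected to do so. Members of a list can vary together, so the excess is not a measure of an effect of the knockdown. Cytokines and chemokines stood farthest out: 12 of 17 genes were at least 2-fold higher and 1, TGFB2 (18.6 against 42.7 FPKM), was lower, with a median of 2.13 above all 10000 random medians. NF-kB pathway feedback genes, which that transcription factor induces and many of which restrain it, had 11 of 19 genes higher and 0 lower, with a median of 1.06, also above all random medians. Among them NFKBIZ stood at 21.6 against 1.93 FPKM, TNFAIP3 at 20.5 against 2.98 FPKM, TRAF1 at 13.3 against 1.55 FPKM and the adhesion receptor ICAM1 at 124 against 26.7 FPKM. Interferon-stimulated genes had 8 of 38 genes higher and 1 lower, with a median of 0.44 at percentile 99.99. ISG15 (53.4 against 18.7 FPKM), PSMB9 (7.30 against 2.02 FPKM) and IFI44 (9.85 against 2.96 FPKM) were higher, and the double-stranded RNA kinase EIF2AK2 was lower, at 8.10 against 17.3 FPKM.

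Apoptosis regulators had 7 of 25 genes higher and 1 lower, with a median of 0.61 at percentile 99.97. The higher ones act in both directions: BAX (23.98 against 6.94 FPKM) and PMAIP1 (75.3 against 23.7 FPKM) promote cell death, while MCL1 (101 against 39.3 FPKM) and BCL2L2 protect from it. BCL2L2 was listed at 14.1 against 1.19 FPKM, but its read-through gene BCL2L2-PABPN1 went the other way, at 0.962 against 7.64 FPKM. Both values are therefore uncertain. Summed they came to 15.0 against 8.83 FPKM, less than 2-fold apart, but a sum of FPKM does not add up reads where lengths differ. Integrated stress response and ATF4 targets had 4 of 25 genes higher and 2 lower, with a median of 0.33 at percentile 98.35; CEBPB stood at 40.6 against 11.5 FPKM and DDIT4, an inhibitor of mTORC1, at 10.5 against 51.9 FPKM. Endoplasmic reticulum chaperones and unfolded protein response genes had 3 of 24 higher and 0 lower, with a median of 0.42 at percentile 98.45, SEC61B at 78.2 against 29.1 FPKM and XBP1 at 18.8 against 8.47 FPKM. The chaperone call ended in 1 alternative, a mean of at least 5 FPKM (percentile 96.67). The stress response call ended there too (68.03), and also at a pseudocount of 5, without the filter on low values, with the length and GC trend removed (94.25) and against random lists matched on coding length (95.94).

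Cytosolic ribosomal proteins were higher as a group, with 28 of 78 genes at least 2-fold higher and 0 lower. Their median of 0.78 exceeded all random medians, and RPL41 (383 against 101 FPKM) and RPS28 (88.9 against 24.7 FPKM) were among the largest differences. Nuclear-encoded respiratory chain subunits had 22 of 76 genes higher and 2 lower, with a median of 0.67, again above all random medians, led by COX8A (323 against 67.1 FPKM) and NDUFA1 (93.4 against 21.1 FPKM). Mitochondrial ribosomal proteins did not go with them: 2 of 67 were higher and 2 lower, with a median of 0.02 at percentile 52.37. The mitochondrially encoded mRNAs had a median of 0.44 at percentile 86.72 over 13 genes, with MT-ND3 at 2400 against 676 FPKM. MT-ATP6 stood at 1340 against 4913 FPKM, while MT-ATP8, which overlaps it, went the other way, at 6228 against 2898 FPKM. Both single values are uncertain because of the overlap. Summed, this pair came to 7568 against 7811 FPKM. Since FPKM are scaled to length, that sum does not show whether reads were exchanged or whether the pair differed. Proteasome subunits had 5 of 34 higher and 1 lower, with a median of 0.36 at percentile 99.11, PSMB4 at 85.2 against 26.6 FPKM and PSME3, an activator subunit, at 10.3 against 28.9 FPKM. This call ended against random lists matched on coding length (percentile 97.33). Over all genes, short transcripts tended to be higher and long ones lower in the siYBX1 library. The median was 0.22 in the shortest of 10 equal length bins and -0.23 in the longest. Without this trend and that of GC content, the ribosomal and respiratory medians were 0.57 and 0.54.

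Lists of the extracellular matrix and its turnover stood apart at the high end, although most of their genes lay within 2-fold. Matrix metalloproteinases and the plasminogen system had 5 of 16 genes higher and 0 lower, with a median of 0.58 at percentile 99.54; the collagenase MMP1 stood at 109 against 27.8 FPKM, the plasminogen activator PLAU at 145 against 37.97 FPKM and ADAM19 at 19.2 against 3.73 FPKM. Collagens, laminins and matrix proteins had 6 of 27 higher and 3 lower, with a median of 0.41 at percentile 99.36, COL4A1 at 30.2 against 7.83 FPKM and LAMA3 at 2.03 against 7.46 FPKM. TGF-beta target genes had 6 of 19 higher and 0 lower, with a median of 0.41 at percentile 98.31, INHBA at 13.2 against 0.816 FPKM and PMEPA1 at 30.6 against 5.72 FPKM. Mesenchymal genes and factors of the epithelial-mesenchymal transition had 3 of 18 higher and 1 lower, with a median of 0.51 at percentile 99.44. In that list TAGLN (25.2 against 9.22 FPKM) and S100A4 (32.8 against 13.7 FPKM) were higher, while ZEB1, a transcription factor that drives the transition, was lower, at 4.74 against 15.1 FPKM. The mesenchymal call ended for genes with a mean of at least 5 FPKM (percentile 96.86), and the TGF-beta call ended at a pseudocount of 0.1 and without the filter on low values.

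The 3 remaining lists at the high end were of autophagy, cholesterol synthesis and histones. Autophagy and lysosome genes had 2 of 38 higher and 0 lower, with a median of 0.39 at percentile 99.85 and GABARAPL1 at 8.59 against 1.52 FPKM. Cholesterol synthesis had 1 of 23 higher, INSIG1 at 36.6 against 9.50 FPKM, and 0 lower, with a median of 0.38 at percentile 99.06. Replication-dependent histones had 4 of 11 higher and 1 lower, with a median of 0.49 at percentile 98.88 and HIST1H2BK at 67.3 against 25.6 FPKM. The histone median was 0.09, at percentile 60.01, once the length and GC trend was removed, the call also ended against random lists matched on coding length (percentile 89.19), and too few histone genes had a mean of at least 5 FPKM to place the list.

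Both lists at the low end concerned nuclear functions. Splicing factors of the hnRNP and SR families had 4 of 33 genes lower and 1 higher, with a median of -0.24 at percentile 2.23. HNRNPUL1 stood at 24.7 against 102 FPKM, HNRNPR at 24.5 against 63.6 FPKM and HNRNPU at 22.1 against 47.4 FPKM, whereas HNRNPA0 was higher, at 20.5 against 8.90 FPKM. Mitosis and G2/M phase genes had 5 of 42 lower and 1 higher, with a median of -0.21 at percentile 2.41. CENPE, a kinetochore motor, stood at 6.40 against 31.7 FPKM, the mitotic transcription factor FOXM1 at 9.44 against 30.4 FPKM and CENPF at 47.2 against 114 FPKM. Both calls ended at a pseudocount of 0.1. The mitosis call also ended without read-through genes, at a mean of at least 5 FPKM (percentile 3.28) and against random lists matched on coding length (percentile 13.14).

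The other lists did not stand apart. Genes often described as YB-1 targets had 1 of 18 genes higher, MYC at 28.4 against 3.92 FPKM, and 0 lower, with a median of -0.15 at percentile 13.12. The p53 targets had a median of 0.30 at percentile 97.22, just short of the threshold. They passed it in 5 alternatives, but stood at percentile 75.44 with a median of 0.19 at a mean of at least 5 FPKM, at 93.49 with the length and GC trend removed and at 89.66 against random lists matched on coding length. Cytosolic heat shock proteins had a median of -0.28 at percentile 4.70, which became -0.41 at percentile 1.96 with the length and GC trend removed. Lists of growth and repair had medians of 0.00 for DNA replication and S phase, -0.50 for cyclin-dependent kinase inhibitors and -0.11 for double-strand break repair. Lists of RNA and translation had medians of 0.23 for initiation and elongation factors, 0.28 for aminoacyl-tRNA synthetases, -0.16 for ribosome biogenesis, -0.08 for stress granule and P-body proteins, -0.07 for m5C and m6A factors and -0.01 for RNA interference machinery. Those of metabolism and stress were 0.33 for glycolysis, 0.09 for fatty acid synthesis and lipid storage, -0.18 for hypoxia response genes, -0.13 for NRF2 antioxidant genes and 0.38 for double-stranded RNA sensors. Those of signalling and adhesion were 0.27 for immediate early genes, 0.11 for integrins and focal adhesion, -0.04 for YAP/TAZ targets, -0.09 for Wnt targets and -0.07 for angiogenesis factors. The YAP/TAZ list stood apart among genes with a mean of at least 5 FPKM, with a median of -0.33 at percentile 1.63. With random lists matched on coding length, glycolysis, aminoacyl-tRNA synthetases, cyclin-dependent kinase inhibitors and double-stranded RNA sensors stood apart, and with unmatched ones glycolysis and the mitochondrially encoded mRNAs did. Epithelial genes had a median of -0.11, luminal breast markers -0.13, basal and myoepithelial markers 0.24, multidrug transporters -0.12 and housekeeping genes 0.33. Of the 5 lists too small to place, values for the cold shock list are given with YBX1, the snoRNA host list held only TAF1D (13.2 against 13.5 FPKM), and no member of the nuclear long noncoding RNA list was listed. Among leukocyte markers CD68 stood at 17.4 against 39.4 FPKM and CD74 at 20.7 against 20.4 FPKM, and among fibroblast and endothelial markers COL1A1 stood at 3.67 against 0.351 FPKM and PDGFRB at 2.22 against 0.861 FPKM.

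**Figure D3:**
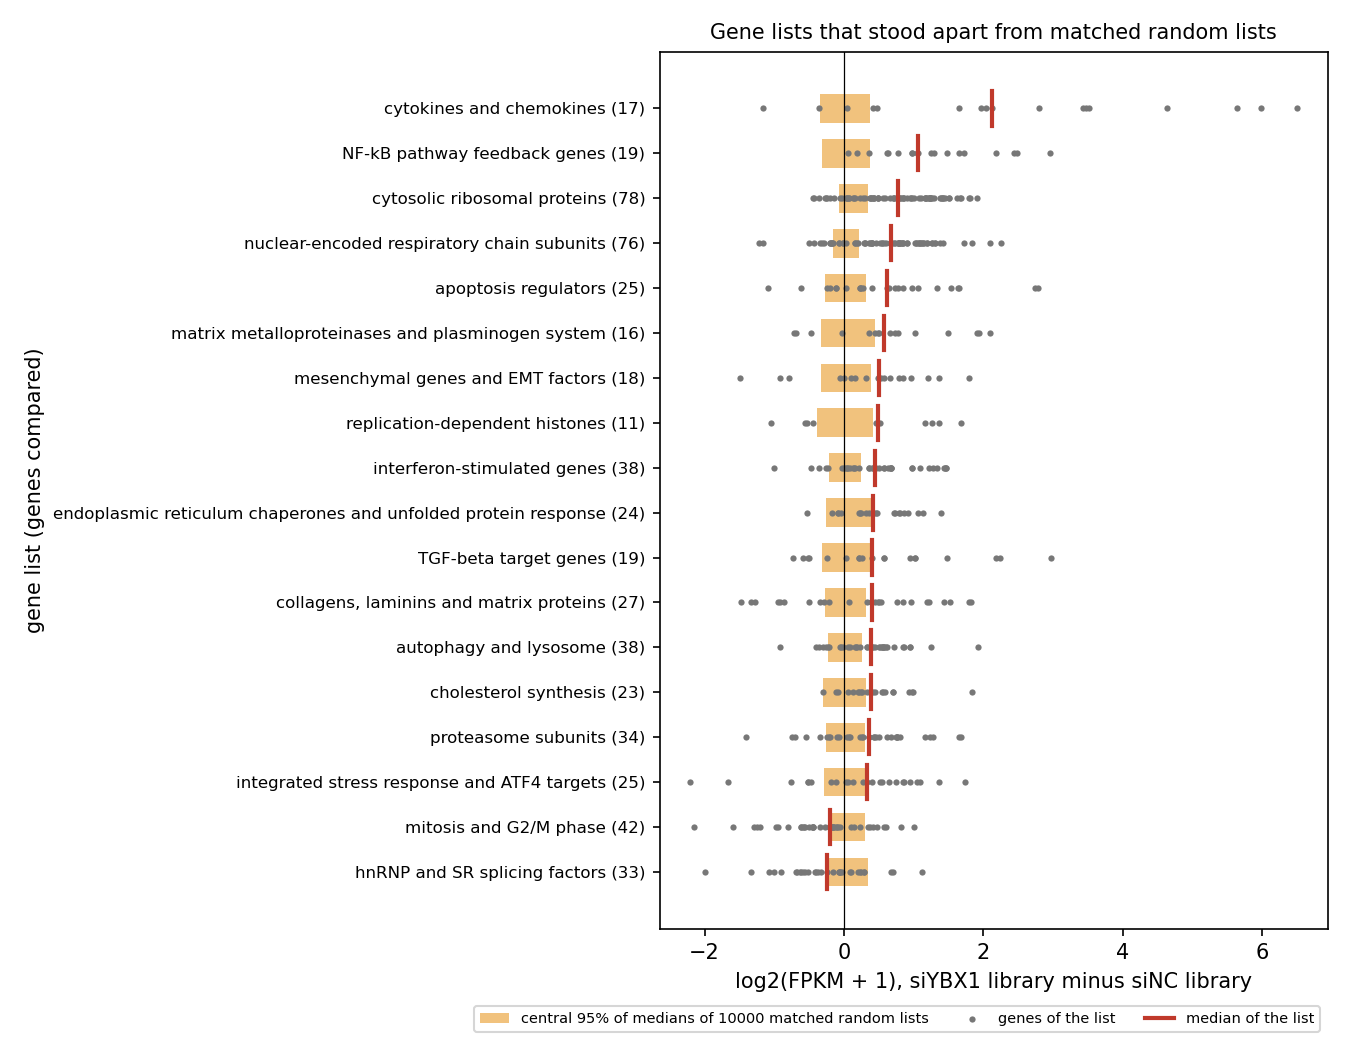
The 18 gene lists that stood apart, with the log2(FPKM + 1) difference, siYBX1 minus siNC, on the x axis: grey points are genes, red bars list medians and orange bands the central 95% of the medians of 10000 random lists matched on expression. Cytokines and chemokines have the highest median, 2.13, and hnRNP and SR splicing factors the lowest, -0.24.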

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

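The hepatocyte, lung and leukocyte marker counts used genes whose values had not been looked at. The test of the loss of YBX1 itself, the tests of genes missing from a table, and the demand that at least 10 leukocyte markers be listed before leukocyte RNA is set aside were chosen after the results were seen.

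Genes listed in 1 library and absent from the table of the other, at 5 FPKM or more, were set apart because the comparison cannot use them. In the siNC library these were ORM1 (87.0 FPKM), NTS (17.5), ORM2 (17.2), FGB (12.04), ALB (10.4), APOA2 (9.92), RBP4 (6.50), AMBP (5.89), FGA (5.86), S100A7 (5.59) and NPIPA5 (5.26). In the siYBX1 library they were the granulocyte growth factor CSF3 (23.3 FPKM), ASB2 (5.71), MRGPRX3 (5.70) and the lung surfactant gene SFTPC (5.61).

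Most of the siNC genes encode plasma proteins made by the liver, and a candidate explanation is RNA from hepatocyte-like cells in that library. Of 24 further hepatocyte markers, 14 were at 0.5 FPKM or more in the siNC library and either lower in the siYBX1 library, as APOE (6.56 against 1.69 FPKM) and APOC1, or missing from its table, as the 12 others, whose level there is unknown. The listing of low genes alone is argued against, more firmly for hepatocyte than for lung markers. Of the hepatocyte markers at 0.5 FPKM or more, 12 of 16 were missing from the siYBX1 table, against 2.92% of all siNC genes at that level. For lung, 4 of 7 were missing from the siNC table, against 154 of 11418 siYBX1 genes. The 4 were low in the siYBX1 library: NAPSA (0.528 FPKM), SFTPA1 (0.537), SFTPB (0.902) and SCGB1A1 (1.09). Other genes matched on FPKM, or on FPKM times transcript length, were drawn 10000 times. At most 0 draws for hepatocyte and 27 for lung markers held as many missing genes. The draws took markers as independent, while genes of 1 tissue can vary together. Against a simple admixture of liver, ORM1 stood far above ALB, and APOA1 was at 0.940 FPKM. SERPINA1 was higher in the siYBX1 library (39.96 against 16.98 FPKM), as was CPS1. That library did not list ALB, so both genes may have another source there and do not decide the question. For lung epithelium in the siYBX1 library 6 of 14 further markers met the same measure while ABCA3, the highest of the 14 in both libraries, was lower there (2.73 against 4.33 FPKM), which leaves it open, as is an effect of the knockdown, which was not tested.

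CSF3 goes with the cytokine and NF-kB genes that were higher in the siYBX1 library. The fitted length and GC trend accounts for little of that pattern, since at least 91.6% of the median was left in both lists after it was removed. RNA from leukocytes stays open: 0 of 20 markers were at 1 FPKM or more and 2-fold higher, but the bound set beforehand counted unlisted markers as not higher and only 5 were listed in the siYBX1 library, where CD68 (17.4 against 39.4 FPKM) and LYZ (0.671 against 1.91 FPKM) were lower, CD74 was nearly equal (20.7 against 20.4 FPKM), and LAPTM5 (31.0 against 16.3 FPKM) and, outside the list, HLA-DRA (12.1 against 0.516 FPKM) were higher. The interferon-stimulated list stood at percentile 99.99, the result set beforehand for an innate response to the transfected nucleic acid. Such a response would have to differ between the reagents because the control library is also labelled with a transfection. The percentile does not single out this cause, since 16 of 47 lists stood apart at the high end. The double-stranded RNA sensors, with a median of 0.38 at percentile 94.10, did not. Loss of YBX1 itself and a response to the reagent cannot be told apart with 1 library per group and 1 reagent against YBX1.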

How the results depend on the processing

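Besides 10 alternatives fixed beforehand, 4 were chosen after seeing the data. The YBX1 level, as a log2 difference, lay between -4.23 and -3.92 in all 6 alternatives run on it, and all 24 ranked genes stayed at least 2-fold apart in the same direction in these. The counts of higher and lower genes stayed within 1.5 times the main 759 and 593 except at other pseudocounts, which by construction widen or shrink the differences of low genes: 925 genes were lower at a pseudocount of 0.1 (1097 higher), and 314 were higher and 209 lower at a pseudocount of 5. Removal of the length and GC trend left 701 higher and 569 lower genes, of which 610 and 474 were shared with the main calls, and leaving out read-through genes and their parts left 713 and 554. Between 14 and 21 lists stood apart, against 18 in the main setting. The 3 scalings move lists and random lists nearly alike, so they do not test the list calls. Of the 18 calls, 13 held at a mean of at least 5 FPKM, where 5 lists, among them the histones, had too few genes to be placed, and 14 with matching on coding length. Leaving the scalings aside, 482 of 512 list medians kept their call, which for most lists was that of not standing apart. The 13 gains came from such lists, and the 17 losses could fall only on the 18 called ones. Of 1284 values of single genes 76 moved by over 1.5-fold, 51 of them at a pseudocount of 5 and 23 at 0.1. No called result reversed its direction, but a pseudocount or a filter cannot change the sign of a gene's difference. Without counts or replicates, neither sampling noise nor the spread between cultures could be set against any difference.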

Other observations

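Several genes of lists that did not stand apart differed by more than 2-fold, some of which, such as JUNB and SLC7A11, also belong to lists that did. The cell cycle inhibitor CDKN1A stood at 53.8 FPKM in the siYBX1 library against 9.44 FPKM in the siNC library, and the p53 targets TNFRSF10B and SESN2 at 21.8 against 5.84 FPKM and 5.50 against 2.04 FPKM. The early response genes JUNB, DUSP5 and IER3 were higher, at 31.0, 37.0 and 241 FPKM against 6.07, 7.67 and 58.4 FPKM. Of the YAP/TAZ targets, CYR61 was higher (699 against 300 FPKM) while F3 and IGFBP3 were lower.

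Hypoxia response genes included 4 lower and 0 higher among 21, with CA9 at 7.65 against 23.9 FPKM and BNIP3 at 59.5 against 143 FPKM. In the NRF2 list the cystine transporter SLC7A11 (3.68 against 13.9 FPKM) and NQO1 (32.5 against 75.7 FPKM) were lower and PRDX1 was higher (301 against 85.6 FPKM). The chaperone HSP90AA1 stood at 195 against 458 FPKM, and the keratin KRT8 at 27.7 against 74.7 FPKM. Among RNA methylation factors YTHDF3 was higher (6.45 against 1.21 FPKM), and YTHDF2 and ZC3H13 were lower (7.02 against 18.6 and 8.33 against 25.04 FPKM).

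The ribosomal protein and respiratory chain mRNAs are mostly short, and short transcripts in general tended to be higher in the siYBX1 library. A length effect of library preparation was therefore a candidate explanation. The test with the length and GC trend was chosen only after the result was seen. For transcript length and GC content, both lists with that trend removed stood at percentile 100 and kept 72.9% and 81.4% of their medians. The fitted trend thus accounts for a part. It used each gene's longest annotated transcript, which need not be the one expressed, so a larger effect of length is not excluded. For short coding sequences, against random lists matched on coding length and expression, both were again at percentile 100, although ribosomal proteins fill some of the bins drawn from. Mitochondrial ribosomal proteins stood at percentile 5.05 in that matching. RNA quality and the knockdown itself were not tested and remain open.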
